A study of Homo sapiens with 15 samples.

How the data were processed

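RNA was sequenced in 15 samples of C4-2, a castration-resistant prostate cancer cell line derived from LNCaP, in 5 lines with 3 libraries each. The lines were a scramble control (Scramble), a line in which PNPLA2, the gene of adipose triglyceride lipase (ATGL), had been knocked out (KO), and the knockout with wild-type ATGL (KO_WT), the S47A protein (KO_S47A) or the S404A protein (KO_S404A) put back. Per the labels, cells were grown with 5 mM glucose and 5% dialyzed serum, RNA was column-purified, poly(A) RNA was selected with oligo-dT beads, and libraries were made with a directional kit. Each genotype is 1 line, and whether a line was cloned or pooled is not given in the sources used here. Nothing in the labels says that the replicates of a line were separate cultures, so p-values measure only the spread between these samples, which may be technical.

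The authors deposited for each library a table of read counts per gene, whole numbers that were not normalized. CASAVA and STAR are named in the submitters' processing notes without versions, and the names of the deposited files point to htseq-count with a UCSC gene set. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and reads of overlapping or antisense gene pairs cannot be told apart. Genes of families with near-identical members, such as the MAGEA, IFITM, KLK, PRSS and histone genes, are uncertain to the extent that the counting split or dropped their shared reads. The deposited tables also hold FPKM values, which the authors scaled to gene length and to the counts of all entries, unassigned reads included. Recomputed that way from the counts they deviated by a relative 9.5e-14 at most, and they were used only for the gene lengths they imply.

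The tables hold 20806 gene entries and 5 entries of unassigned reads. Unassigned reads made up 13.2% to 20.6% of each library, of which reads in no annotated feature were 8.21% to 15.2% of the library, and they were left out of library sizes and tests. Counts in genes totalled 40846694 to 64345775 per library. Counts were 0 in every library for 2512 entries, 206 symbols stood on several entries and 32 entries had no symbol. Gene identifiers matched the reference table of gene names for 20623 entries. The libraries of a group were compared pairwise over genes with at least 20 counts, and chi-square per degree of freedom ran from 8.11 to 239, so none differed by as little as sampling noise and all 15 were kept as separate samples.

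Counts were analysed in R 4.3.3. Genes with low counts were removed with edgeR's filterByExpr, which kept 14246 genes, and library sizes were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 15 libraries with edgeR 4.0.16, so that the 5 groups shared 1 estimate of the spread with 10 residual degrees of freedom, and 8 comparisons between groups were tested. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and adjusted p-values of genes come from this test unless another tool is named. Errors of log2 fold changes are standard errors (SE), intervals are 95%, and group levels are TMM-scaled CPM as mean ± SD. The SE is an approximation, the absolute log2 fold change divided by the square root of the F statistic of the edgeR test. Intervals were built from it. At this depth and number of libraries the 95% interval of a gene's log2 fold change had a median halfwidth of 0.36.

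Gene lists were tested with camera on voom values (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over all tested lists and the 8 comparisons. Members were counted as risen or fallen by the edgeR calls, and again with p adjusted over the list alone. The same test with a correlation estimated from the data was run for each list, and of the 46 list calls 2 hold with it, the interferon response in KO minus Scramble and in KO_WT minus Scramble. The lists were glycolysis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid droplets and lipolysis, triglyceride and phospholipid synthesis, nuclear respiratory chain subunits, the tricarboxylic acid cycle, androgen receptor targets, proliferation, the ATF4 and amino acid response, endoplasmic reticulum chaperones, the interferon response, the hypoxia response, mesenchymal and motility genes, luminal epithelial genes, basal or stem-like epithelial genes, neuroendocrine genes, lysosome and autophagy, NRF2 oxidative stress, p53 targets, NF-kB and inflammatory cytokines, immediate early genes, replication-dependent histones, and marker lists of stroma, endothelium and blood and of non-prostate epithelial lines. Mitochondrially encoded genes were not analysed here because 0 of them were measured.

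Genes named in the text follow a rule. For each comparison it takes PNPLA2, then the 5 risen and 5 fallen genes with the largest log2 fold change among called genes with a named symbol, CPM ranges that do not overlap and a mean of at least 10 CPM in the higher group, and up to 3 called members of each list with the lowest p. A further part, for genes changed by the knockout, called in the opposite direction in KO_WT minus KO and called again between KO_WT and KO_S47A, took 0 genes. Genes outside the rule are said to be chosen after their values were seen. Some genes are not reported here. The grouping, the comparisons, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except the alternatives that keep only the libraries numbered 1 and 2 or leave out the genes of chromosome 22, which were chosen after seeing the data.

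The alternatives were the Wald test of DESeq2 1.42.0 with its own size factors, RLE size factors in edgeR, no filter on low counts, a fit on the libraries of the groups compared only, the replicate number as a block (8 residual degrees of freedom), leaving out each library in turn, an estimated correlation for the lists, the libraries numbered 1 and 2 only, and the genes of chromosome 22 left out. Genes were assigned to chromosomes, and ordered along them, by gene identifier in a reference table of RefSeq genes on GRCh38.p14, which matched 14093 of the 14246 tested genes. Chromosomes with at least 60 tested genes were compared. Each gene of chromosome 22 was tested against the median of its 370 genes in a t test with the approximate SE given above, adjusted over those genes. Whether replicate numbers pair the libraries was checked on the correlation of same-numbered libraries' deviations from their group means, with 0.1 as the minimum for every pair. The lowest of the 3 correlations was 0.13 in KO minus Scramble, 0.14 in KO_WT minus KO, 0.15 in KO_S47A minus KO, 0.27 in KO_WT minus KO_S47A, 0.19 in KO_S404A minus KO_WT and in KO_S404A minus KO_S47A, and 0.23 in KO_WT minus Scramble. These 7 comparisons were taken as paired from the values alone, since the labels do not say what a number marks. A library numbered 3 that stands apart gives libraries 1 and 2 a shared opposite deviation from their group mean. Positive correlations for numbers 1 and 2 can thus arise without pairing by number. With the line as a term, edgeR called 6451 genes between the libraries numbered 3 and the others, and 0 between those numbered 2 and 1. In KO_WT minus KO and in KO_S47A minus KO only 3 of 6 libraries correlated best with their own number, so the pairing there is weak. KO_S404A minus KO did not pair, with 2 of 6.

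The tests were run on simulated counts for KO minus Scramble, drawn for 14143 genes of which 100 were changed by a log2 of 1 and 100 by a log2 of 2. A further set of genes was shifted by a smaller amount for the list test, and calls among them count as neither recovered nor false. All shifted genes were drawn from genes above a minimum mean count, so recovery at low counts was not tested. The edgeR fit called 78 and 95 of the 100 and 100 changed genes, with 1 false call among 180. With the replicate block it called 92 and 100, with 13 false calls among 222, and DESeq2 called 85 and 99, with 4 false calls among 199. The simulated means carried the same shift by replicate number in every line, and their spread came from the blocked fit. The model of the block thus held by construction, and its recovery and false calls need not carry over to the real libraries. Plots were drawn with matplotlib 3.10.9.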

Results

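Gene expression was measured by poly(A) RNA sequencing in 5 lines of C4-2, a castration-resistant prostate cancer cell line, described by the submitters as isogenic, with 3 libraries per line. ATGL, encoded by PNPLA2, releases the first fatty acid from stored triglyceride. The design asks what its loss changes and which changes go back when an ATGL protein is added. The proteins were wild-type ATGL, S47A, which lacks the catalytic serine and is described as lipolytically inactive, and S404A. Counts in genes totalled 40846694, 49253301 and 51662088 in Scramble and 47325563, 55731053 and 54173068 in KO. They totalled 47895553, 41521069 and 46147301 in KO_WT, 54933402, 53922842 and 49885735 in KO_S47A, and 61352325, 64345775 and 50971324 in KO_S404A.

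In each of the 5 lines the library numbered 3 had the lowest mean of the ATF4 and amino acid response list and the highest of the proliferation list. In KO_S404A, library 2 was no closer to library 1 than to library 3, with a chi-square per degree of freedom over genes of 148 and 140. Against the libraries numbered 1 and 2, the median gene of the ATF4 and amino acid response list lay at a log2 difference of −1.13, and that of the endoplasmic reticulum chaperones at −0.57. The median was −0.26 for p53 targets and −0.09 for NRF2 genes. It was 0.15 for glycolysis, 0.18 for cholesterol synthesis and 0.94 for proliferation.

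PNPLA2 followed the labels. It stood at 48.9 ± 4.76 CPM (SD, n = 3) in Scramble, with libraries between 45.3 and 54.3. In KO it stood at 11.3 ± 1.99 CPM (n = 3), between 9.11 and 13.0. The level was 220 ± 18.1 CPM in KO_WT (206.6 to 240.5), 129 ± 30.6 CPM in KO_S47A (110.2 to 164.5) and 413 ± 98.3 CPM in KO_S404A (303 to 493), n = 3 each. The log2 fold change was −2.11 (SE 0.20, adjusted p = 3.54e-05) in KO minus Scramble. It was 2.17 (SE 0.20, adjusted p = 2.71e-05) in KO_WT minus Scramble. A transcript with a frameshift can still give reads, so the remaining level in KO says nothing about the protein.

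**Figure D1:**
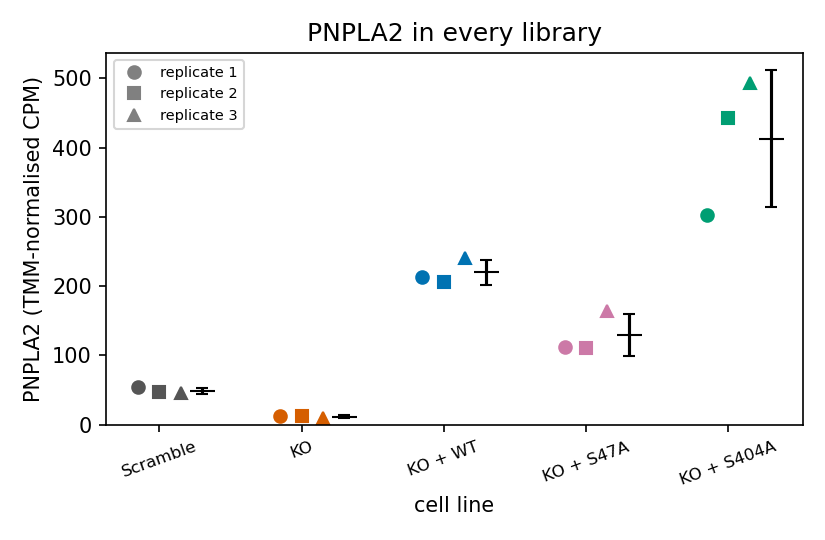
PNPLA2 in TMM-scaled CPM (linear axis from 0) for each of the 15 libraries by line, with circles, squares and triangles for replicates 1, 2 and 3 and a black bar for the mean ± SD of 3 libraries. The KO libraries lie between 9.11 and 13.0 CPM, below the Scramble libraries at 45.3 to 54.3, and the addback libraries lie between 110.2 and 493.

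Between KO and Scramble, LPL, the lipoprotein lipase that releases fatty acids from circulating triglyceride, was almost lost. It stood at 0.36 ± 0.12 CPM in KO against 11.9 ± 2.99 in Scramble (n = 3 each, log2 fold change −5.04, SE 0.56, adjusted p = 0.000168). SYT4, a synaptotagmin of vesicle traffic, fell from 31.9 ± 6.71 to 0.47 ± 0.19 CPM (−6.07, SE 0.37). The collagen gene COL12A1 fell from 61.8 ± 16.7 to 1.61 ± 0.014 CPM (−5.26, SE 0.29). CCDC85A (−5.21, SE 0.23) and CAMK2N1, an inhibitor of a calmodulin-dependent kinase (−5.04, SE 0.57), completed the 5 largest falls among called genes with a mean of at least 10 CPM in the higher group and CPM ranges that did not overlap. MAGEA10, a cancer-testis antigen, rose 17.4-fold from 3.92 ± 0.35 to 68.3 ± 2.03 CPM (adjusted p = 1.46e-11). EPHA3, an ephrin receptor, rose 7.63-fold from 62.4 ± 6.05 to 476 ± 39.7 CPM. RALYL (3.17, SE 0.35), the adhesion receptor GPR133, now named ADGRD1 (2.61, SE 0.27), and the protocadherin PCDH7 (2.36, SE 0.19) also rose. The adjusted p of these genes was at most 0.000183.

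**Figure D2:**
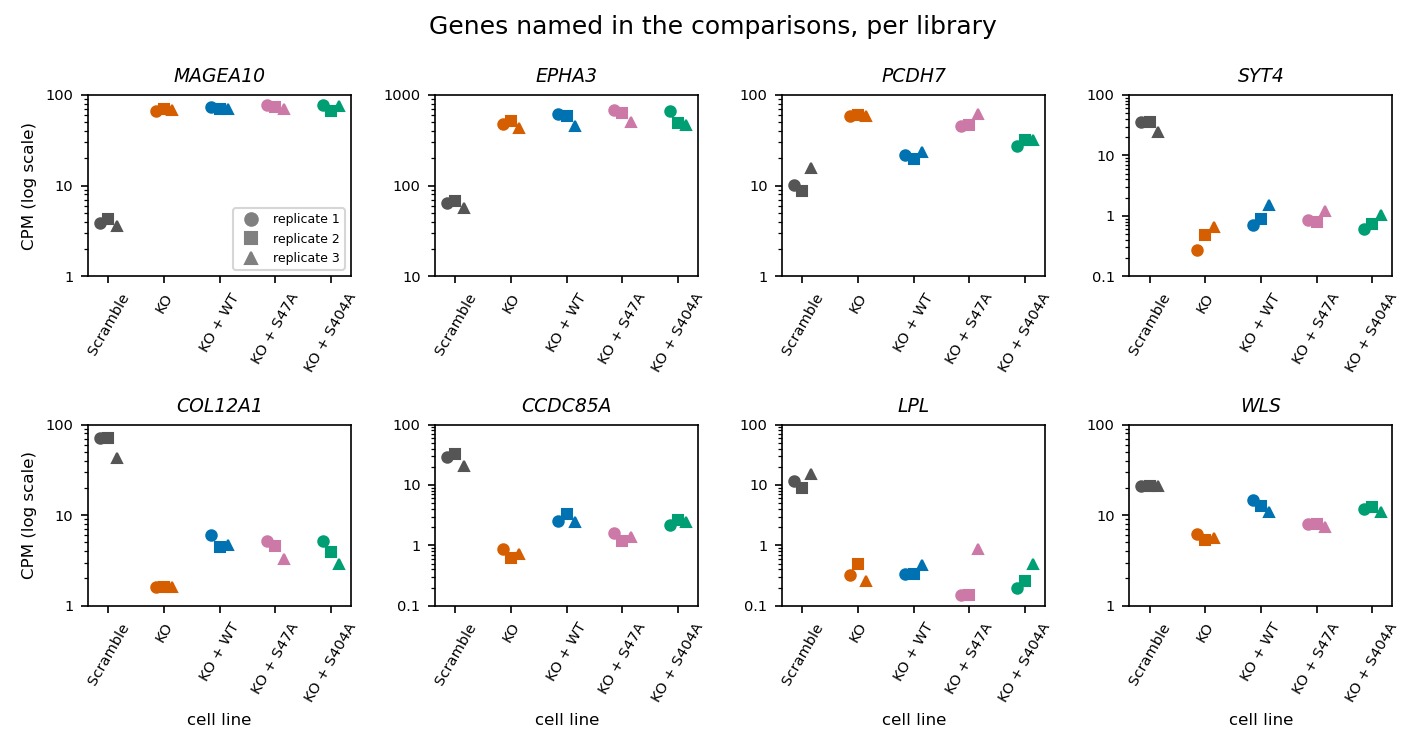
CPM on a log axis of 8 genes in each library by line, with circles, squares and triangles for replicates 1, 2 and 3. MAGEA10 and EPHA3 are higher, and SYT4, COL12A1, CCDC85A, LPL and WLS lower, in KO than in Scramble, while PCDH7 is 59.1 ± 0.77 CPM in KO and 21.8 ± 1.91 in KO_WT.

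By edgeR, 383 of 14246 genes were called in KO minus Scramble, 138 higher and 245 lower, of which 177 changed at least 2-fold. The replicate block gave 1181 calls, 467 higher and 714 lower, and kept the 383. DESeq2 called 693 genes and the libraries numbered 1 and 2 alone gave 770. The count was 206 without Scramble 1, 205 without Scramble 2, 215 without KO 1, 209 without KO 2 and 213 without KO 3.

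Chromosome 22, chosen after its values were seen, was lower as a whole in the knockout. Of its 370 tested genes 43 fell and 1 rose, APOBEC3F (0.95, chosen after its values were seen), and 89.2% had a log2 difference below 0 in KO minus Scramble, against 37.1% to 52.3% on the 22 other chromosomes compared. The median of its genes was −0.32 in KO, −0.38 in KO_WT, −0.33 in KO_S47A and −0.28 in KO_S404A, each minus Scramble, while the medians of the other chromosomes in KO minus Scramble lay between −0.01 and 0.07. It was −0.29 over its genes that were not called. Tested against the chromosome's median, 1 of the 44 called genes, APOBEC3F, differed from it (adjusted p = 0.00243), and 20 did at an unadjusted p under 0.05. The furthest fall among the 44 was that of SLC5A1 (−2.24, chosen after its values were seen). Each of 19 stretches of up to 20 neighbouring genes had a median between −0.57 and −0.24. Relative to the mean of all libraries its median gene stood at 0.25 to 0.28 in the 3 Scramble libraries and at −0.10 to 0.03 in the 12 others. With the genes of chromosome 22 left out, an alternative chosen after seeing the data, 325 genes were called in KO minus Scramble, 126 higher and 199 lower.

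Lipid genes changed singly between KO and Scramble. ACADL, a long-chain acyl-CoA dehydrogenase, rose from 8.62 ± 1.88 to 38.7 ± 4.65 CPM (n = 3 each, adjusted p = 3.94e-06), while SLC25A20, the carnitine-acylcarnitine carrier, fell by 0.60 on the log2 scale (adjusted p = 0.016). They were the 1 risen and 1 fallen of 28 fatty acid oxidation genes (1 and 2 adjusted over the list alone, camera adjusted p = 0.443). The desaturase gene SCD5 rose (log2 fold change 0.69, adjusted p = 0.00809), 1 of 18 fatty acid synthesis genes (1 adjusted over the list alone, camera adjusted p = 0.456). MGLL, which cleaves monoacylglycerol, rose (0.65, adjusted p = 0.0119), 1 of 16 lipid droplet and lipolysis genes (1 adjusted over the list alone, camera adjusted p = 0.29). The acyltransferase gene AGPAT4 rose (1.58, adjusted p = 0.00752), 1 of 26 genes of triglyceride and phospholipid synthesis (1 adjusted over the list alone, camera adjusted p = 0.904). In the tricarboxylic acid cycle 2 of 22 fell (2 adjusted over the list alone, camera adjusted p = 0.159). IDH3G was among them (−0.35, adjusted p = 0.0366). Genes chosen after their values were seen that did not pass were FASN (−0.08, adjusted p = 0.955), CPT1A (−0.35, adjusted p = 0.0553, and 0.0182 with the replicate block), PLIN2 (0.32, adjusted p = 0.939), LIPE (−0.12, adjusted p = 0.915) and ABHD5 (0.07, adjusted p = 0.841). Leaving out 1 library ended the call of SCD5 (Scramble 1, adjusted p = 0.0646) and of MGLL (Scramble 1, 0.0717, Scramble 2, 0.0776, or KO 3, 0.0648). It ended that of SLC25A20 (Scramble 1, 0.0554, Scramble 2, 0.0885, KO 1, 0.0836, or KO 3, 0.0555) and of IDH3G for each library but Scramble 3 (0.0964 to 0.142). IDH3G was also lost in the fit of the 2 groups only (0.0697).

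Interferon response genes were higher in KO than in Scramble. Of 38 members 7 rose and 0 fell, and 15 rose and 0 fell when adjusted over the list alone (camera adjusted p = 5.27e-10, adjusted p = 0.00157 with an estimated correlation). Their mean log2 CPM relative to all libraries lay between 0.05 and 0.11 in the 3 KO libraries and between −0.58 and −0.38 in the 3 Scramble libraries. SAMD9, an antiviral factor, stood at 1.55 ± 0.61 against 0.14 ± 0.10 CPM (log2 fold change 3.45, adjusted p = 0.00375). IFITM1, which hinders viral entry, stood at 8.18 ± 0.47 against 4.12 ± 0.40 CPM (0.99, adjusted p = 0.0183), and IFIT2 at 0.96 ± 0.11 against 0.34 ± 0.19 (1.53, adjusted p = 0.0244). ISG15 (0.15, adjusted p = 0.806), chosen after its values were seen, did not pass. The list was called in each of 10 other settings at the preset correlation (adjusted p 7.14e-11 to 3.38e-07). Under the replicate block 11 members rose and 1 fell (adjusted p = 0.0115 with an estimated correlation). IFITM1 was lost without Scramble 1 (0.108), Scramble 2 (0.0591), Scramble 3 (0.0568), KO 2 (0.0756) or KO 3 (0.0648). IFIT2 was lost without Scramble 2 (0.135), Scramble 3 (0.102), KO 1 (0.0765), KO 2 (0.0906) or KO 3 (0.0513), in the fit of the 2 groups only (0.11) and with the libraries numbered 1 and 2 only (0.0847).

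Androgen receptor targets were lower in KO. Of 32 members 7 fell and 2 rose, and 11 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.000197, adjusted p = 0.836 with an estimated correlation). TRPM8, a cation channel of prostate epithelium, stood at 34.8 ± 1.74 against 107 ± 11.0 CPM (log2 fold change −1.62, adjusted p = 2.77e-05). The kallikrein gene KLK2 stood at 470 ± 58.9 against 872 ± 51.3 CPM (−0.89, adjusted p = 0.00193). MAF, a transcription factor, rose from 15.0 ± 0.91 to 29.2 ± 7.59 CPM (0.96, adjusted p = 0.00973) and was lost without Scramble 2 (0.0546). KLK3, which encodes prostate-specific antigen and was chosen after its values were seen, had a log2 fold change of −0.60 (adjusted p = 0.142, and 0.00504 with the replicate block). In the luminal list AGR2, a disulfide isomerase of the secretory pathway, fell from 37.5 ± 3.31 to 2.83 ± 0.91 CPM. It was the 1 fallen of 21 (3 fallen and 1 risen adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.698 with an estimated correlation). The luminal call was lost without Scramble 3 (0.0857) or KO 2 (0.0636).

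In the mesenchymal list fibronectin FN1 fell from 150 ± 22.5 to 33.8 ± 5.51 CPM (adjusted p = 1.56e-06), and thrombospondin THBS1 from 176 ± 43.2 to 29.1 ± 2.16 CPM (adjusted p = 3.16e-05). They were 2 of 16 members (2 adjusted over the list alone, camera adjusted p = 0.379), and the list's median was 0.07 while its mean (−0.09) and test pointed down. Of 6 basal genes ITGB4 rose (log2 fold change 0.54, adjusted p = 0.00683) and the keratin KRT14 fell (−1.04, adjusted p = 0.00315), with 2 risen and 3 fallen adjusted over the list alone (camera adjusted p = 0.588). Of 9 markers of non-prostate epithelial lines TBX5 rose, at 1.98 ± 0.22 against 1.05 ± 0.17 CPM, and MAGEA4 fell, at 0.019 ± 0.0013 against 1.27 ± 0.36 CPM. The counts were the same adjusted over the list alone (camera adjusted p = 0.995, median 0.02, mean and test down). Stroma, endothelium and blood markers had 0 of 6 changed (0 adjusted over the list alone, camera adjusted p = 0.729). ITGB4 was lost without Scramble 2 (0.0546). TBX5 was lost without any 1 of the 6 libraries (0.0548 to 0.166), without the filter on low counts (0.0586), in the fit of the 2 groups only (0.108) and with the libraries numbered 1 and 2 only (0.139).

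Chaperones, the ATF4 response and proliferation had 0 members called in KO minus Scramble, and the libraries numbered 3 also differed in them. Chaperones had a median of −0.48 (0 of 21 called, 3 of them on chromosome 22, camera adjusted p = 0.000185, adjusted p = 0.847 with an estimated correlation), and the libraries numbered 3 differed by −0.57. The ATF4 response had a median of −0.36 (0 of 34 called, camera adjusted p = 0.0463, adjusted p = 0.887 with an estimated correlation), and those libraries differed by −1.13. Proliferation had a median of 0.28 (0 of 35 called, camera adjusted p = 0.0646), and those libraries differed by 0.94. The respiratory chain (50 genes, median −0.06, camera adjusted p = 0.0111) and hypoxia genes (21 genes, median −0.15, camera adjusted p = 0.0261) were lower as lists, with 0 members called. Both calls were lost with adjusted p = 0.847 and 0.836 with an estimated correlation. In these lists the libraries numbered 3 differed by 0.01 (camera adjusted p = 0.577) and −0.13 (camera adjusted p = 0.413). Adjusted over the list alone, 1 hypoxia gene fell and 0 members of the other 4 lists changed. With the block 6 chaperones, 5 hypoxia genes and 3 ATF4 genes fell and 1 proliferation gene rose. The block added the list calls of proliferation (up, 4.45e-06), lysosome and autophagy (down, 0.0217), NRF2 (down, 0.021) and histones (down, 0.0195), which were lost with adjusted p = 0.67 to 0.783 with an estimated correlation. ATF4 was lost without Scramble 1 (0.379), Scramble 2 (0.53) or KO 3 (0.75) and with RLE size factors (0.0673). The respiratory chain was lost without Scramble 1 (0.0546) or KO 1 (0.705), and hypoxia without Scramble 1 (0.183) or KO 1 (0.115). The mean of the respiratory chain list relative to all libraries was −0.14 in KO 1 against 0.10 and 0.003 in KO 2 and 3, and the count-weighted mean gene length was 3827 bases in KO 1 against 3622 and 3667.

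The remaining lists were not called in KO minus Scramble without the block. Lysosome and autophagy had 1 of 33 fallen (1 adjusted over the list alone, camera adjusted p = 0.0763), SQSTM1, the autophagy receptor p62 (log2 fold change −0.71, adjusted p = 0.0387). The camera adjusted p was 0.849 for glycolysis (24 genes), 0.172 for cholesterol synthesis (24) and 0.997 for neuroendocrine genes (9). It was 0.17 for NRF2 (27), 0.156 for p53 targets (20), 0.729 for NF-kB (12), 0.389 for immediate early genes (22) and 0.0763 for histones (10). No member of these 8 lists was called, and adjusted over the list alone 1 glycolysis gene and 1 neuroendocrine gene fell. Median and mean differed in sign for glycolysis (0.02 and −0.02, test down), neuroendocrine genes (0.14 and −0.17, test up) and NF-kB genes (0.14 and −0.11, test up). SQSTM1 was lost without Scramble 1 (0.109), Scramble 2 (0.155), KO 1 (0.0886), KO 2 (0.118) or KO 3 (0.169).

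Wild-type ATGL in the knockout went with few called genes beyond PNPLA2 itself (log2 fold change 4.28, SE 0.22, adjusted p = 3.49e-07). WLS, which carries Wnt proteins to the cell surface, rose from 5.65 ± 0.44 to 12.7 ± 1.91 CPM (n = 3 each, 1.17, SE 0.12, adjusted p = 0.000964). PCDH7 fell from 59.1 ± 0.77 to 21.8 ± 1.91 CPM (−1.44, SE 0.18, adjusted p = 0.00763). CCDC85A, chosen after its values were seen, rose from 0.74 ± 0.13 to 2.74 ± 0.45 CPM (1.90, adjusted p = 0.00247). With the block COL12A1 (1.63, adjusted p = 0.000318) and the potassium channel gene KCNH8 (1.14, adjusted p = 0.000527) also rose. Both were chosen after their values were seen. By edgeR 3 genes were higher and 1 lower in KO_WT, and the block gave 10 and 5. DESeq2 gave 8 calls, the fit of the 2 groups only 2 and the libraries numbered 1 and 2 only 43. PCDH7 was lost without KO 2 (0.051), KO_WT 1 (0.0768) or KO_WT 2 (0.102), and WLS (0.107) and CCDC85A (0.151) in the fit of the 2 groups only.

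As a list, proliferation was lower in KO_WT than in KO (median −0.41, camera adjusted p = 2.15e-05), as was glycolysis (−0.21, 0.000382), both lost with an estimated correlation (adjusted p = 0.847 and 0.836). Chaperones (0.39, 1.04e-05), the ATF4 response (0.50, 0.0156), lysosome and autophagy (0.10, 0.0185) and the respiratory chain (0.07, 0.0438) were higher. These 4 calls were lost with adjusted p = 0.836 to 0.872 with an estimated correlation. Of the members of the 6 lists 0 were called, 0 adjusted over the list alone. The libraries numbered 3 differed by 0.94 in proliferation, 0.15 in glycolysis, −0.57 in chaperones and −1.13 in the ATF4 response. With the block 34 proliferation genes fell and 21 ATF4 genes rose when adjusted over the list alone. The block ended the respiratory chain call (0.106) and added histones (up, 0.0325, adjusted p = 0.688 with an estimated correlation). Lipid droplets and lipolysis (0.549) and fatty acid oxidation (0.604) were not called, with 0 members changed and 0 adjusted over the list alone. The respiratory chain, whose mean was −0.14 in KO 1 against 0.10 and 0.003 in KO 2 and 3, was lost without KO 1 (0.944, direction reversed), KO_WT 1 (0.104) or KO_WT 3 (0.0583) and with the libraries numbered 1 and 2 only (0.0699). ATF4 was lost without KO 3 (0.671), KO_WT 1 (0.508) or KO_WT 2 (0.399), and lysosome and autophagy without KO 2 (0.0622).

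The S47A protein gave 1 call by edgeR in the knockout, PNPLA2 itself (log2 fold change 3.51, SE 0.21, adjusted p = 2.99e-06). WLS (0.46, adjusted p = 0.274), CCDC85A (0.92, adjusted p = 0.274) and PCDH7 (−0.22, adjusted p = 0.485), chosen after their values were seen, did not pass. With the block WLS (adjusted p = 0.00991) and CCDC85A (adjusted p = 0.0109) were called. Chaperones were higher as a list (median 0.91, camera adjusted p = 8.02e-12), as were the ATF4 response (0.84, 2.15e-05) and lysosome and autophagy (0.10, 0.0463). These 3 calls were lost with adjusted p = 0.836 to 0.847 with an estimated correlation. Proliferation (−0.70, 1.87e-08) and glycolysis (−0.26, 0.0048) were lower, both lost with adjusted p = 0.847 with an estimated correlation. No member was called, and adjusted over the list alone 19 of 21 chaperones rose and 0 members of the other 4 lists changed. The libraries numbered 3 differed by −0.57 in chaperones, −1.13 in the ATF4 response, 0.94 in proliferation and 0.15 in glycolysis.

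With the replicate block 21 of 21 chaperones, 31 of 34 ATF4 genes and 10 of 33 lysosome and autophagy genes rose in KO_S47A, and 35 of 35 proliferation genes and 10 of 24 glycolysis genes fell. Examples chosen after their values were seen are HERPUD1, of endoplasmic reticulum quality control (log2 fold change 1.66, block adjusted p = 0.00261), and the cystine transporter SLC7A11 (1.20, 0.00277). Others are the stress cytokine GDF15 (1.62, 0.00295) and the mitotic checkpoint kinase BUB1B (−1.06, 0.00378). The block also called p53 targets (up, 0.035, adjusted p = 0.783 with an estimated correlation), in which the libraries numbered 3 differed by −0.26. The block gave 3150 calls, 1510 higher and 1640 lower, against 1 without it, where 2397 genes had an unadjusted p under 0.05. The blocked calls numbered 69 without the KO_S47A and KO pair numbered 1, 1 without pair 2 and 3433 without pair 3. DESeq2 gave 33 calls and the libraries numbered 1 and 2 only 3098. Without KO_S47A 3 there were 15 calls, and lysosome and autophagy was lost without KO 1 (0.0526), KO 2 (0.0966), KO_S47A 1 (0.053) or KO_S47A 3 (0.106).

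**Figure D3:**
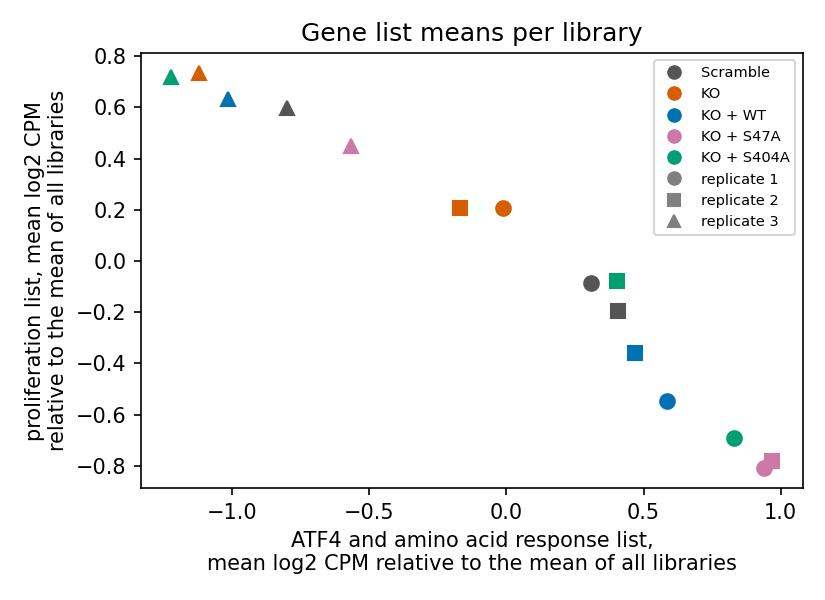
Mean log2 CPM of the ATF4 and amino acid response list (horizontal) and of the proliferation list (vertical) in each library, both relative to the mean of all libraries, with colours for lines and circles, squares and triangles for replicates 1, 2 and 3. The triangles lie at low ATF4 and high proliferation means, and KO_S47A spans −0.57 to 0.97 on the horizontal axis.

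With the S404A protein PNPLA2 rose (log2 fold change 5.19, SE 0.23, adjusted p = 4.71e-08) and WLS rose to 11.6 ± 0.83 CPM (1.04, SE 0.12, adjusted p = 0.00365). CCDC85A, chosen after its values were seen, rose to 2.41 ± 0.22 CPM (1.71, adjusted p = 0.00735). PCDH7, chosen likewise, had a log2 fold change of −0.96 (adjusted p = 0.344, and 0.0015 with DESeq2). As lists, cholesterol synthesis (median −0.19, camera adjusted p = 4.32e-05), the respiratory chain (−0.10, 1.46e-06) and proliferation (−0.31, 3.11e-05) were lower, each lost with an estimated correlation (adjusted p = 0.836 to 0.847). The ATF4 response (0.49, 0.00153), chaperones (0.41, 2.15e-05), lysosome and autophagy (0.11, 0.0277) and the 6 stroma, endothelium and blood markers (0.35, 0.0351) were higher. These 4 calls were lost with adjusted p = 0.698 to 0.847 with an estimated correlation. No member of the 7 lists was called, and adjusted over the list alone 1 cholesterol gene fell. The libraries numbered 3 differed by 0.18 in cholesterol synthesis, 0.94 in proliferation, −1.13 in the ATF4 response and −0.57 in chaperones.

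KO_S404A minus KO thus had 3 calls by edgeR. DESeq2 gave 8, the fit of the 2 groups only 1 and the libraries numbered 1 and 2 only 403. There were 2 without KO 3, 2 without KO_S404A 2 and 1 without KO 2. WLS was lost without KO 2 (0.0559) and in the fit of the 2 groups only (0.316). CCDC85A was lost without KO 2 (0.0995), KO 3 (0.0809) or KO_S404A 2 (0.0577) and in that fit (0.542). Without KO_S404A 1 the calls of proliferation (0.613), chaperones (0.439), ATF4 (0.696) and lysosome and autophagy (0.453) were lost. ATF4 was also lost without KO 3 (0.355) or KO_S404A 2 (0.146), lysosome and autophagy without KO 1 (0.0828) or KO 2 (0.0535), and the respiratory chain without KO_S404A 2 (0.0743), whose mean of that list was −0.28 against −0.04 and −0.05 in KO_S404A 1 and 3. The stroma list was lost without any 1 of the 6 libraries (0.134 to 0.363).

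Of the 383 genes called in KO minus Scramble, 4 were called in the opposite direction with wild-type ATGL, namely PNPLA2, WLS, PCDH7 and CCDC85A. Their return was partial for WLS (62.0% of the difference), PCDH7 (61.0%) and CCDC85A (36.4%), and all 3 were still called in KO_WT minus Scramble (log2 fold change −0.72, 0.92 and −3.32, adjusted p = 0.00334, 0.0123 and 5.78e-07). PNPLA2, which the addback itself supplies, went past its Scramble level (202.8%). With S47A 1 went back (PNPLA2) and with S404A 3 (PNPLA2, WLS and CCDC85A). The amount of addback mRNA differed too, with PNPLA2 at 220 ± 18.1 CPM in KO_WT, 129 ± 30.6 in KO_S47A and 413 ± 98.3 in KO_S404A. WLS had fallen in KO from 20.9 ± 0.13 to 5.65 ± 0.44 CPM (n = 3 each, chosen after its values were seen). Other settings start from other sets of genes called in KO minus Scramble. Under the replicate block, with 1181 such genes, 8 went back with wild-type ATGL and 320 with S47A. Unchanged groups simulated against the same KO libraries gave 0 in each of 20 draws, and leaving PNPLA2 out independent lists would share 0.0439, 0 and 0.0343 genes, against 3, 0 and 2 observed. The 2 genes other than PNPLA2 called with both wild-type ATGL and S404A compare with a simulated highest of 0 and an independent overlap of 0.00028. The simulated groups were drawn from the observed KO means, so they leave out the chance deviations of the KO libraries. The 3 KO libraries are too few to split, so part of these excesses may come from the shared controls. Fits of the 2 groups only, with 417 genes called in KO minus Scramble, gave 2 reversed genes for wild-type ATGL and 1 for S404A. DESeq2, with 693, gave 6 each for wild-type ATGL, S47A and S404A, so the 3 proteins did not differ in this count. With the libraries numbered 1 and 2 only, 26, 304 and 103 of 770 were reversed. Leaving out KO_S47A 3 gave 4 for S47A, and leaving out KO 2 gave 1 for S404A.

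Leaving PNPLA2 out, the median gene called in KO minus Scramble moved back by 7.7% of its difference with wild-type ATGL (quartiles −11.4% and 26.6%). It moved back by 11.1% with S47A (−8.3% and 30.0%) and by 5.9% with S404A (−6.5% and 22.8%), against simulated medians of 0%, −0.2% and −0.2%. The simulated addback libraries were drawn from the observed means of the same KO libraries, so a return near 0% was built in. They cannot show how much return the shared KO libraries alone would give. Across the 383 genes, which are not independent replicates, the KO minus Scramble difference was also set against differences that share no library with it. Its Pearson correlation was −0.178 (Spearman −0.081) with KO_S47A minus KO_WT and −0.19 (Spearman −0.059) with KO_S47A minus KO_S404A. In fits of the 2 groups only they were 0.012 and −0.034, and with the libraries numbered 1 and 2 only the second was −0.341. Leaving out 1 library gave −0.278 (without KO_WT 1) to −0.001 (without KO 3) for the first and −0.271 (without Scramble 3) to −0.001 (without KO 3) for the second.

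Between KO_WT and KO_S47A 0 genes differed by edgeR, with 309 at an unadjusted p under 0.05, 4 calls by DESeq2, 2 with the libraries numbered 1 and 2 only and 3 with the replicate block. The 3 were chosen after their values were seen. PCDH7 was lower in KO_WT at 21.8 ± 1.91 against 50.8 ± 8.93 CPM (n = 3 each, block adjusted p = 0.00233), and the ephrin receptor gene EPHA6 at 8.82 ± 1.71 against 17.6 ± 3.2 CPM (0.00357). WLS was higher at 12.7 ± 1.91 against 7.74 ± 0.35 CPM (0.0271). As lists, chaperones (median −0.53, camera adjusted p = 5.27e-10), the ATF4 response (−0.36, 0.000493) and p53 targets (−0.15, 0.0156) were lower in KO_WT, each lost with an estimated correlation (adjusted p = 0.836 to 0.847). Proliferation (0.27, 5e-04), androgen receptor targets (0.10, 0.00561) and the respiratory chain (0.05, 0.00498) were higher. These 3 calls were lost with adjusted p = 0.836 to 0.847 with an estimated correlation. Of the 6 lists 0 members were called, 0 adjusted over the list alone. With the block 14 chaperones and 21 ATF4 genes fell when adjusted over the list alone, and NRF2 genes were called (down, 0.0368, adjusted p = 0.67 with an estimated correlation). The libraries numbered 3 differed by −0.57, −1.13, −0.26, 0.94 and −0.09 in chaperones, ATF4, p53, proliferation and NRF2 genes. Without KO_WT 3 proliferation (0.497) and ATF4 (0.826) turned direction and p53 was lost (0.482). Without KO_S47A 1 proliferation (0.448), ATF4 (0.169), p53 (0.174) and androgen receptor targets (0.121) were lost. Without KO_S47A 2 proliferation (0.318), ATF4 (0.274), p53 (0.47), androgen receptor targets (0.177) and the respiratory chain (0.47) were lost. The respiratory chain was also lost without KO_WT 1 (0.163).

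Between KO_S404A and KO_WT 0 genes differed by edgeR, with 1239 at an unadjusted p under 0.05, 0 calls by DESeq2 and 0 with the block. PNPLA2 had a log2 fold change of 0.91 (95% interval 0.49 to 1.32, adjusted p = 0.547). Respiratory chain genes were lower in KO_S404A as a list (median −0.19, 0 of 50 called, 0 adjusted over the list alone, camera adjusted p = 3.89e-11, adjusted p = 0.836 with an estimated correlation). Relative to all libraries the list's mean was −0.28 in KO_S404A 2 against −0.04 and −0.05 in KO_S404A 1 and 3, and without KO_S404A 2 the adjusted p was 4.32e-08. That library also had the lowest share of reads in no annotated feature of the 15, 8.21%, against 14.1% and 13.2% in KO_S404A 1 and 3. Its count-weighted mean gene length was the highest of the 15, 3886 bases against 3658 and 3727. Glycolysis was higher (0.10, 0 of 24 called, 1 risen adjusted over the list alone, camera adjusted p = 0.0464, adjusted p = 0.847 with an estimated correlation), and the libraries numbered 3 differed in it by 0.15. The block added cholesterol synthesis (down, 0.0154) and androgen receptor targets (down, 0.0366), lost with adjusted p = 0.749 and 0.783 with an estimated correlation. Glycolysis was lost without KO_WT 1 (0.316), KO_WT 2 (0.17), KO_S404A 2 (0.205) or KO_S404A 3 (0.457). It was also lost with RLE size factors (0.0562) and with the libraries numbered 1 and 2 only (0.0621).

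Between KO_S404A and KO_S47A 1 gene differed by edgeR, PNPLA2 (log2 fold change 1.68, SE 0.20, adjusted p = 0.0109), with 939 at an unadjusted p under 0.05 and 2 calls by DESeq2. The block gave 2, adding EPHA6 (−0.81, 0.04, chosen after its values were seen). As lists, chaperones (median −0.46, camera adjusted p = 1.26e-07), the respiratory chain (−0.13, 2.15e-05), cholesterol synthesis (−0.13, 0.00219) and the ATF4 response (−0.35, 0.0277) were lower in KO_S404A. These 4 calls were lost with adjusted p = 0.836 to 0.878 with an estimated correlation. Proliferation (0.37, 0.00146) and glycolysis (0.14, 0.0293) were higher, both lost with adjusted p = 0.847 with an estimated correlation. No member of the 6 lists was called, and adjusted over the list alone 1 cholesterol gene fell. With the block 19 chaperones and 21 ATF4 genes fell and 20 proliferation genes rose when adjusted over the list alone, and p53 targets were called (down, 0.0217, adjusted p = 0.783 with an estimated correlation). Those numbered 3 differed from the other libraries by −0.57, 0.18, −1.13, 0.94, 0.15 and −0.26 in chaperones, cholesterol synthesis, ATF4, proliferation, glycolysis and p53 genes.

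The PNPLA2 call between KO_S404A and KO_S47A was lost without KO_S47A 1 (0.164), KO_S47A 2 (0.158), KO_S404A 2 (0.0969) or KO_S404A 3 (0.051) and in the fit of the 2 groups only (0.922), which leaves 0 calls. Without KO_S404A 3 proliferation (0.958) and ATF4 (0.343) turned direction and glycolysis was lost (0.251). Without KO_S47A 1 proliferation (0.174), ATF4 (0.627) and glycolysis (0.311) were lost, and without KO_S47A 2 they were lost at 0.203, 0.791 and 0.14. Glycolysis was lost without KO_S404A 2 (0.156), and the respiratory chain (0.178) and cholesterol synthesis (0.578) without KO_S47A 3. Without KO_S404A 2, where its mean was −0.28 against −0.04 and −0.05 in KO_S404A 1 and 3, the respiratory chain had an adjusted p of 0.0236. Cholesterol synthesis was also lost without KO_S404A 1 (0.147) and with the libraries numbered 1 and 2 only (0.0766).

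The wild-type addback line differed from Scramble in most genes named in KO minus Scramble. MAGEA10 (log2 fold change 4.18, SE 0.10), RALYL (3.74, SE 0.36), EPHA3 (3.14, SE 0.17) and GPR133 (2.94, SE 0.27) were higher in KO_WT. GPR126, an adhesion receptor now named ADGRG6, stood at 189 ± 58.6 against 40.5 ± 7.23 CPM (n = 3 each, 2.22, adjusted p = 0.00196). LPL (−4.96, SE 0.56), SYT4 (−4.93, SE 0.34), CAMK2N1 (−3.90, SE 0.54), the pseudokinase gene TRIB2 (−3.73, SE 0.29) and COL12A1 (−3.61, SE 0.26) were lower. Interferon genes had 11 of 38 risen and 0 fallen (18 and 0 adjusted over the list alone, camera adjusted p = 8.02e-12, adjusted p = 0.00136 with an estimated correlation). Among them were SAMD9 (3.35), IFITM1 (1.20) and IFITM3 (0.49), and 16 rose with the block (adjusted p = 0.00925 with an estimated correlation). Androgen receptor targets had 4 of 32 fallen and 1 risen (5 and 2 adjusted over the list alone, camera adjusted p = 0.000284, adjusted p = 0.836 with an estimated correlation). TRPM8 (−1.41) and the transporter gene ABCC4 (−0.53) fell and MAF (0.94) rose. ACADL (1.98) and SCD5 (0.92) rose, and FN1 (−2.46), THBS1 (−3.08) and AGR2 (−2.74) fell.

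In glycolysis 2 of 24 genes fell in KO_WT minus Scramble (4 adjusted over the list alone, camera adjusted p = 0.00203, adjusted p = 0.847 with an estimated correlation), and the libraries numbered 3 differed by 0.15. They were the lactate transporter gene SLC16A3 (log2 fold change −1.34, adjusted p = 0.0174) and the hexokinase gene HK2 (−0.41, adjusted p = 0.0427). The tricarboxylic acid cycle (1 of 22 fallen, camera adjusted p = 0.00897), the luminal list (1 of 21 fallen, 0.0261), cholesterol synthesis (0 of 24, 0.0123) and NRF2 genes (0 of 27, 0.0301) were also lower, with the same counts adjusted over the list alone. These 4 calls were lost with adjusted p = 0.698 to 0.836 with an estimated correlation. In cholesterol synthesis the libraries numbered 3 differed by 0.18 and in NRF2 genes by −0.09. The block added proliferation (down, 0.00484) and p53 targets (up, 0.0297), lost with adjusted p = 0.844 and 0.783 with an estimated correlation, where those libraries differed by 0.94 and −0.26. SLC16A3 was lost without Scramble 1 (0.0511), Scramble 3 (0.0765), KO_WT 1 (0.0867) or KO_WT 2 (0.0875). HK2 was lost without Scramble 1 (0.145), Scramble 2 (0.0513), Scramble 3 (0.135), KO_WT 1 (0.161) or KO_WT 2 (0.128) and in the fit of the 2 groups only (0.0736). The luminal list was lost without KO_WT 3 (0.0786), and NRF2 without Scramble 1 (0.0619), Scramble 2 (0.208) or KO_WT 3 (0.295). With the libraries numbered 1 and 2 only HK2 (0.0657), the luminal list (0.108) and NRF2 (0.0599) were not called.

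By edgeR 494 genes were called in KO_WT minus Scramble, 215 higher and 279 lower. The block gave 1429, 653 higher and 776 lower, and DESeq2 868. The count was 280 without Scramble 1, 317 without Scramble 2, 272 without Scramble 3, 240 without KO_WT 1 and 278 without KO_WT 2. On chromosome 22 there were 68 lower and 1 higher, and 398 genes were called with its genes left out, 196 higher and 202 lower. Of the 383 genes called in KO minus Scramble, 273 were also called here with the same sign, 106 higher and 167 lower, and 382 had the same sign. Of the 273, 28 lie on chromosome 22. Both comparisons use the Scramble libraries. Unchanged groups simulated against them gave at most 0 shared calls and a median of 49.1% with the same sign in 10 draws. Independent lists would share 2.08 higher and 4.8 lower genes. These simulated groups were drawn from the observed Scramble means, so they leave out the chance deviations of the Scramble libraries. The 3 Scramble libraries are too few to split, so part of the excess may come from the shared controls.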

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

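The tests in this part were planned before the data were examined, except those with the libraries numbered 1 and 2 only, which were chosen after the results were seen. The results below stand out because 2 addback lines differ from each other in the test of that difference. Groups of 3 libraries were not tested for single outlying samples.

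Relative to KO_S47A, the median log2 difference in KO_WT was −0.53 for endoplasmic reticulum chaperones, −0.36 for the ATF4 and amino acid response, −0.15 for p53 targets, 0.27 for proliferation, 0.10 for androgen receptor targets and 0.047 for respiratory chain subunits. Relative to KO_WT, the median in KO_S404A was −0.19 for respiratory chain subunits and 0.10 for glycolysis. Relative to KO_S47A, the median in KO_S404A was −0.46 for chaperones, −0.35 for the ATF4 response, 0.37 for proliferation, 0.14 for glycolysis, −0.13 for cholesterol synthesis and −0.13 for respiratory chain subunits. With a correlation estimated from the data, 0 of these 14 list differences were called, with adjusted p between 0.836 and 0.878. With the libraries numbered 1 and 2 only, glycolysis in KO_S404A minus KO_WT (0.0621) and cholesterol synthesis in KO_S404A minus KO_S47A (0.0766) were not called. Without KO_WT 3, ATF4 (0.826) and proliferation (0.497) turned direction in KO_WT minus KO_S47A, and without KO_S404A 3 they did (0.343 and 0.958) in KO_S404A minus KO_S47A. Those fits keep KO_S47A 3, so the shift of the libraries numbered 3 enters the difference.

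The PNPLA2 transcript itself differed between KO_S404A and KO_S47A by a log2 fold change of 1.68 (SE 0.20, edgeR adjusted p = 0.0109), so the lines compared carry different amounts of the addback mRNA. Its call was lost without KO_S47A 1 (0.164), KO_S47A 2 (0.158), KO_S404A 2 (0.0969) or KO_S404A 3 (0.051) and in the fit of the 2 groups only (0.922).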

How the results depend on the processing

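The settings with the libraries numbered 1 and 2 only and with the genes of chromosome 22 left out were chosen after the results were seen, and the other settings were planned. A count is taken as kept within 1.5 times its value, and a correlation within 1 SD of its values with 1 library left out (0.084 and 0.081). By these bounds RLE size factors, no filter on low counts and leaving out chromosome 22 kept each of the 14 results, the PNPLA2 call included. Calls were then 403, 354 and 325 in KO minus Scramble and 518, 442 and 398 in KO_WT minus Scramble, and the first correlation was −0.176, −0.128 and −0.18. The replicate block gave 1181 calls in KO minus Scramble, 15 in KO_WT minus KO, 3150 in KO_S47A minus KO, 14 in KO_S404A minus KO, 3 in KO_WT minus KO_S47A, 2 in KO_S404A minus KO_S47A and 1429 in KO_WT minus Scramble, with 8, 320 and 8 of its 1181 KO minus Scramble genes reversed in KO_WT, KO_S47A and KO_S404A. In KO_S404A minus KO the numbers do not pair the libraries, since the 3 same-number correlations were 0.17, 0.02 and 0.51. There 2 of 6 libraries correlated best with their own number, against 3 of 6 in KO_WT minus KO and in KO_S47A minus KO. DESeq2 gave 693, 8, 33, 8, 4, 2 and 868 calls in the same order, with 6 genes reversed in each of KO_WT, KO_S47A and KO_S404A. Fits of the 2 groups only gave 2 calls in KO_WT minus KO, 1 in KO_S404A minus KO and 0 in KO_S404A minus KO_S47A, with 2 genes reversed in KO_WT and 1 in KO_S404A. There the correlation of the knockout change with KO_S47A minus KO_WT was 0.012, reversed in sign, and with KO_S47A minus KO_S404A −0.034. The libraries numbered 1 and 2 gave 770 calls in KO minus Scramble, 43 in KO_WT minus KO, 3098 in KO_S47A minus KO, 403 in KO_S404A minus KO and 2 in KO_WT minus KO_S47A, with 26, 304 and 103 of the 770 reversed and a correlation of −0.341 with KO_S47A minus KO_S404A. The cause of these shifts was not tested, except for KO_S47A minus KO under the block.

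With 1 library left out, calls ranged from 205 to 291 in KO minus Scramble, 1 to 15 in KO_S47A minus KO, 1 to 4 in KO_S404A minus KO, 0 to 1 in KO_S404A minus KO_S47A and 240 to 440 in KO_WT minus Scramble. Reversed genes ranged from 1 to 4 in KO_S47A and 1 to 4 in KO_S404A, and the correlations from −0.278 to −0.001 and from −0.271 to −0.001. 5 list calls turned direction without 1 library, and the cause was not tested. Leaving out KO_WT 3 or KO_S404A 3 keeps KO_S47A 3. The shift of the libraries numbered 3 (−1.13 in ATF4 and 0.94 in proliferation) then enters the difference from KO_S47A. The adjusted p ranged from 7.74e-05 to 0.944 (without KO 1) for the respiratory chain in KO_WT minus KO, from 9.27e-10 to 0.497 (without KO_WT 3) for proliferation and 9.28e-08 to 0.826 (without KO_WT 3) for ATF4 in KO_WT minus KO_S47A, and from 1.58e-10 to 0.958 (without KO_S404A 3) for proliferation and 4.69e-06 to 0.791 for ATF4 in KO_S404A minus KO_S47A, where it was 0.343 and reversed without KO_S404A 3.

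Of the 46 list calls, 2 held and 44 were lost with an estimated correlation, 45 held with the block and 1 did not, 44 held with RLE size factors and 2 did not, 41 held with the libraries numbered 1 and 2 only and 5 did not, and 46 held without chromosome 22. The block added the list calls given with each comparison and changed no other list call. Of the 112 values of named genes, 112 kept their call with RLE size factors, 109 without chromosome 22, which removes 3, 102 with DESeq2, which called 10 more, 80 with the block, which called 32 more, and 98 in fits of the 2 groups, which lost 14. At 40846694 to 64345775 counts per library, the 95% interval of a gene's log2 fold change in KO minus Scramble had a median halfwidth of 0.36.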

Other observations

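The tests of library numbers, of the addback mRNA, of the number of libraries, of a difference between lines, of chromosome 22, of depth, of a separate round and of numbered pairs were chosen only after the results were seen, as were the tests by library number in the next paragraph. The tests of length and GC content, of the shift shared with the libraries numbered 3 and of other splits had their outcome bounds written first.

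The 5 libraries numbered 3 differed from the 10 numbered 1 and 2 in many genes. With the line as a term, edgeR called 6451 genes, 3156 higher and 3295 lower in the libraries numbered 3, of which 599 changed at least 2-fold, against 0 between the libraries numbered 2 and 1 with edgeR. Genes of the response to amino acid shortage were lower: 33 of 34 ATF4 list genes fell and 0 rose (camera adjusted p = 3.88e-25, adjusted p = 0.547 with an estimated correlation). ASNS, asparagine synthetase, stood at 136 ± 36.9 against 565 ± 142 CPM (SD, n = 5 and 10, log2 fold change −2.05), CHAC1, which degrades glutathione, at 12.1 ± 5.66 against 73.2 ± 20.9 (−2.61) and SLC7A11 at 91.5 ± 34.4 against 416 ± 126 (−2.19). Chaperones had 18 of 21 fallen (3.15e-07, adjusted p = 0.681 with an estimated correlation) and p53 targets 13 of 20 fallen and 2 risen (0.00579, adjusted p = 0.681 with an estimated correlation).

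Genes of DNA replication and division were higher in the libraries numbered 3, with 35 of 35 proliferation genes risen (camera adjusted p = 1.73e-22, adjusted p = 0.547 with an estimated correlation). CCNE2, cyclin E2, stood at 78.7 ± 6.25 against 29.9 ± 10.0 CPM (log2 fold change 1.48, adjusted p = 1.02e-06) and PCNA, the replication clamp, at 381 ± 26.2 against 199 ± 43.4 (0.97). TXNIP, an inhibitor of glucose uptake, stood at 10.7 ± 3.62 against 3.30 ± 0.78 CPM (1.68, adjusted p = 1.28e-05). Glycolysis had 11 of 24 risen and 2 fallen (0.00751, adjusted p = 0.681 with an estimated correlation), cholesterol synthesis 13 of 24 risen and 2 fallen (0.0245, adjusted p = 0.681 with an estimated correlation) and NRF2 genes 12 of 27 fallen and 3 risen (0.0245, adjusted p = 0.547 with an estimated correlation). These genes were chosen after their values were seen.

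A pattern to follow up is that the libraries numbered 3 stand apart. Depth is argued against, because the library numbered 3 had the highest total of its line in 1 of 5 lines. A bias by gene length or GC content is argued against, because the ATF4 list kept a median of −1.14 (quartiles −1.95 and −0.94) once that trend, 1.2% of the variance, was removed. A separate culture or library round may be the source. That the ATF4 list was lowest in the library numbered 3 in 5 of 5 lines is the pattern itself, so it does not favour this source. The labels give no round, so a culture and a library difference cannot be told apart. No biological explanation was tested, since the design gives no group that follows the numbers.

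Another pattern is the rise from 1 call to 3150 in KO_S47A minus KO with the replicate number as a block. The shift that sets the libraries numbered 3 apart, estimated in the other 3 lines, correlated at −0.86 (Spearman −0.88) across 3131 of the called genes, of which 3022 had the opposite sign, and at −0.65 across all 13962 genes tested in both, so KO_S47A may differ from KO in part along that axis. Leaving out numbered pair 1 gave 69 blocked calls, pair 2 gave 1 and pair 3 gave 3433, so the count rests on both the pairs numbered 1 and 2. An effect of the S47A protein stays open and untested, since the line, its culture state and its libraries cannot be told apart with 1 line per genotype.

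The third pattern is that most differences between KO and Scramble remain in the wild-type addback. That the addback mRNA was not made is argued against, because PNPLA2 stood 4.5-fold above Scramble in KO_WT. A full return hidden by too few libraries is argued against for 273 of the 383 genes. These were called in KO_WT minus Scramble with the same sign. The count cannot speak to a partial return, since WLS, PCDH7 and CCDC85A went back in part and were still called there. For the shift of chromosome 22 as a whole, with a median of −0.32 over all its tested genes, a different number of copies in Scramble and in the knockout-derived lines may be the source, and an effect of ATGL loss on single genes is argued against, because 89.2% of its genes lay below 0 against at most 52.3% on another, though DNA was not measured. Of its 44 called genes 1, APOBEC3F, differed from that median and rose, so the shift is not the whole cause for that gene. The other 43 were not told apart from the median at an adjusted p under 0.05. At an unadjusted p under 0.05, 20 of the 44 differed, so effects on single genes there stay open. For the 339 called genes elsewhere a difference between the lines that does not depend on ATGL is a candidate explanation, with a median return of 6.2% leaving PNPLA2 out (7.7% with chromosome 22), but a lasting effect of ATGL loss predicts the same and the 1 line per genotype cannot tell them apart.

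For each comparison the 6 libraries were also split in the other ways, 10 splits with the real one, which are too few for a share under 0.05. The real split gave 383 calls against a highest other of 1 in KO minus Scramble, 494 against 0 in KO_WT minus Scramble, 4 against 0 in KO_WT minus KO, 1 against 0 in KO_S47A minus KO and 3 against 0 in KO_S404A minus KO, so that 1 of 10 splits gave as many calls in each. It gave 0 against 0 in KO_WT minus KO_S47A, where 10 of 10 splits gave as many. In KO_S404A minus KO_WT, where 10 of 10 splits gave as many, the real split gave 0 and the split that sets KO_WT 1, KO_WT 2 and KO_S404A 1 against the rest gave 1634. In KO_S404A minus KO_S47A, where 2 of 10 splits gave as many, the real split gave 1 and the split of KO_S47A 1, KO_S47A 2 and KO_S404A 1 against the rest gave 3108. Such splits point to a structure of the samples other than the lines. The real splits of the 2 comparisons gave 0 and 2 blocked calls. The block was not fitted to the splits with 1634 and 3108 calls, which put same-numbered libraries on 1 side. Reversed genes were 4, 1 and 3 against a highest other of 0 each, with 1 of 10 splits as large, and the correlations of −0.178 and −0.19 were reached by 4 of 10 splits each, with 0.29 and −0.317 as the farthest of the others. In the comparisons that passed the minimum correlation for pairing, 4 splits part all same-numbered pairs. The others of these 4 exchange libraries within pairs and gave at most 0 blocked calls, against real counts of 1181, 15, 3150, 3, 0, 2 and 1429.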
